A study of Mus musculus with 6 samples.

How the data were processed

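Gene expression was measured on Affymetrix MoGene 2.0 ST arrays in CD8+ T cells from mice, with 3 arrays of wild-type (WT) cells and 3 of cells lacking TET2 in the T lineage (TET2cKO). Per the labels' protocols, sorted naive cells were cultured for 3 days on plate-bound antibodies to CD3 (1 µg/ml) and CD28 (5 µg/ml) with human IL-2 at 100 U/ml. Labelled cDNA was made from 200 ng of total RNA per sample, and 5.5 µg of it was fragmented. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 3 samples of a genotype came from separate animals, so p-values measure only the spread between these samples, which may be technical.

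The deposited value table holds log2 values of 33793 probe sets per array, each summarising the probes along a transcript. Its scale was not named in the file. The authors' deposited ratio of TET2cKO over WT equalled 2 to the power of the difference of the group means within a relative difference of 5.7e-05, which sets the base. Background correction, normalization between arrays and the software used are not given in the sources used here. The authors' workbook holds the same log2 values, with a largest difference of 0.0. It heads each TET2cKO column with its own number, and whether that number marks an animal is not given. Per the file headers, it adds a linear ratio, a signed fold change, an unadjusted p-value, a q-value in percent and a score for each probe set. The test behind the authors' p-value, q-value in percent and score is not named in the header. The medians of the 6 arrays lay between 5.84 and 5.97 on the log2 scale. The number of arrays limits the precision. The median standard error of a log2 difference was 0.112.

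Gene symbols came from the workbook, where 29121 probe sets listed 1 symbol, 3080 several and 1592 none. The gene assignment text of 19190 probe sets ended at 255 characters, so some probe sets with 1 symbol may match further genes. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6, which also gave the positions. Of the probe sets with 1 symbol, 24582 matched by symbol, 1333 by Entrez ID, 88 by synonym and 5 by RefSeq accession, and 3113 kept the workbook's symbol. Probe sets with no symbol or several were left out of the main test. Probe sets whose mean over the 6 arrays lay under the 25th percentile of named probe sets, a log2 value of 4.673, were also left out. A gene with several probe sets was represented by the brightest, which left 21566 genes.

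Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors of log2 differences are standard errors (SE) from this fit, and adjusted p-values are limma's unless another test is named. For single values, an exact permutation test was used; 3 against 3 samples cannot give a two-sided p below 0.1. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 28 lists that had at least 5 measured members. The correlation estimated from each list, and limma's fry, were alternatives.

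The design, the 32 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Tet2, Tet1 and Tet3, and the 12 genes with the largest change per direction among those past the threshold without overlap between genotypes. Where fewer than 6 passed in a direction, it named the 6 with the smallest p among non-overlapping genes with unadjusted p under 0.05. Genes with symbols of predicted, RIKEN or cDNA genes, antigen-receptor segments and small RNA genes were left out of that part. It also named up to 4 members with the smallest p of each list, and 15 genes of effector and memory differentiation, of which 1 is not reported here. The alternatives were a block for the replicate number, leaving out each array, the workbook's values, quantile normalization, median centring, other filters on dim probe sets, the mean of a gene's probe sets, an intensity trend with robust eBayes, array weights and other thresholds. A test without genes within 25 Mb of Tet2 and one over all probe sets were added after seeing the data.

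The limma test was tested on simulated data for TET2cKO against WT over 21566 genes, with the real means and spreads and 200 changed genes, 10 times. It recovered 44% of genes changed 1.5-fold, 81% at 2-fold, 99% at 4-fold and 100% at 8-fold, and 4.5% of its calls were unchanged genes. With nothing changed it called 0 genes in each simulation. The simulated genes varied independently, unlike real ones. Random draws and positions along the genome were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.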

Results

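Transcript levels were measured in 6 samples of mouse CD8+ T cells, 3 WT (C57BL/6) and 3 TET2cKO, in which Cre driven by the Cd4 promoter deletes a floxed Tet2. TET2 is an enzyme that oxidises 5-methylcytosine in DNA. All samples came from sorted naive cells activated in culture for 3 days through CD3 and CD28 with IL-2. The design has a single comparison, TET2cKO against WT, which asks how gene expression in activated CD8+ T cells differs without TET2. Cre and the floxed allele are described for TET2cKO only, and the labels do not give the backcross of that line. Effects of Cre, of the floxed allele or of strain background therefore cannot be told apart from loss of TET2. WT replicate 1 stood apart from the other arrays. Across the tested genes, which are not independent replicates, its log2 values correlated with theirs at 0.9884 to 0.9911, and those of all other pairs at 0.9921 to 0.9952. Its root mean square deviation from its group mean was 0.177, against 0.116 to 0.144 for the others.

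The Tet2 transcript itself (chromosome 3, 133463677 to 133545136, GRCm38.p6) had a mean log2 value of 9.19 ± 0.08 (SD, n = 3) in TET2cKO and 9.48 ± 0.29 (SD, n = 3) in WT. The difference of -0.29 ± 0.14 (SE) did not pass limma's test (adjusted p = 0.616), and the exact permutation p was 0.1, the smallest that 3 against 3 can give. Each TET2cKO array was lower than each WT array, but without WT replicate 1, at 9.82, the difference was -0.12. The probe set summarises the whole transcript, and probes outside the deleted part can keep their signal, so this value is a weak check of the genotype labels. Tet1 differed by 0.12 ± 0.12 (adjusted p = 0.781) and Tet3 by 0.08 ± 0.12 (adjusted p = 0.86).

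Gbp2b, which encodes an interferon-inducible guanylate-binding GTPase, had the largest log2 difference among the genes tested. It was 26.5-fold higher in TET2cKO, with log2 values of 9.85 ± 0.42 (SD, n = 3) against 5.12 ± 0.13 in WT. Rwdd3, whose product enhances conjugation of SUMO, rose 2.15-fold, and Mcoln3, which encodes an endolysosomal cation channel, rose 2.53-fold. Glrp1 fell by 1.85 on the log2 scale, Mcub (Ccdc109b in the deposited workbook), which encodes an inhibitory subunit of the mitochondrial calcium uniporter, fell by 1.56, and Rbm44 fell by 0.87. In each of these genes all 3 TET2cKO arrays lay on one side of all 3 WT arrays. The WT mean of Gbp2b lies near the limit of the brightness filter, a log2 value of 4.673, and the TET2cKO mean of Glrp1, 4.09, lies under it. No detection call was used here, so the sizes of these 2 differences are uncertain where one side may be background.

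**Figure D1:**
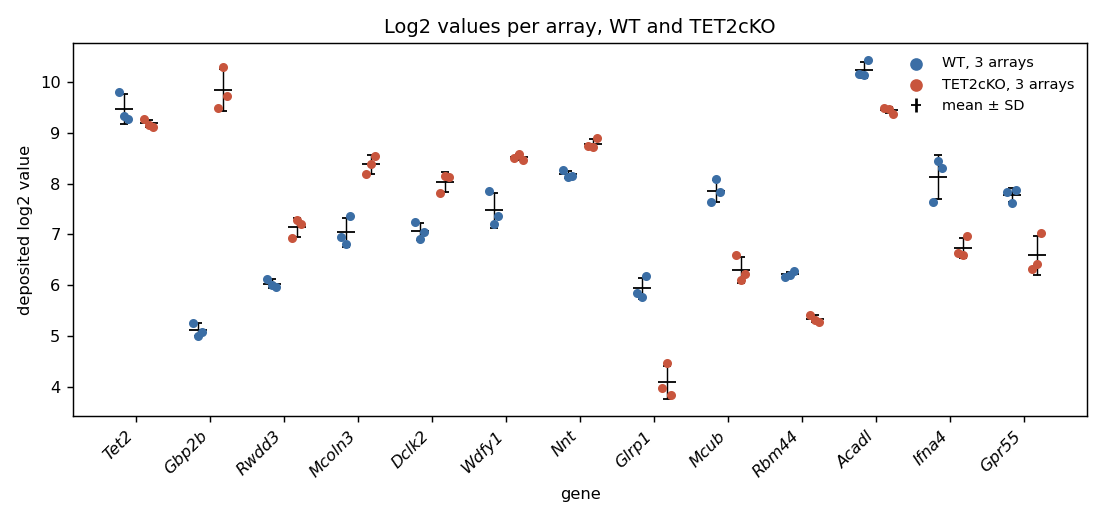
Deposited log2 value (vertical axis) of Tet2 and of the 12 genes named for their genotype difference (horizontal axis), with 1 point per array, WT in blue and TET2cKO in red, and black bars for mean ± SD (n = 3). Gbp2b moves from a WT mean of 5.12 to 9.85 in TET2cKO, while Tet2 differs by -0.29.

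These 6 genes and Gm22121, a predicted gene singled out after its values were seen, were the 7 of 21566 genes past limma's adjusted p of 0.05, with 4 higher and 3 lower. The adjusted p was 3.28e-05 for Gbp2b, 0.0165 for Glrp1 and Gm22121, 0.0202 for Mcub, 0.0219 for Rwdd3 and Rbm44, and 0.0436 for Mcoln3. Gm22121 rose by 1.54 ± 0.14 (SE). At an unadjusted p under 0.05 there were 1793 genes (8.31%), 1027 higher and 766 lower. The genotypes did not overlap in 2983 genes (13.8%), where chance gives 10%. The 7 were also the 7 probe sets with a q-value of 0.0% in the authors' deposited table. Gbp2b passed whichever array was left out, with an adjusted p of at most 0.000794. After quantile normalization 4 genes passed, 3 higher and 1 lower, without Rbm44 and Mcub (adjusted p = 0.0598) and Mcoln3 (0.0896). Without WT replicate 1 there were 9 genes, and Mcoln3 did not pass (adjusted p = 0.127). Without WT replicate 2 Gbp2b was the 1 gene left, and the adjusted p of the other 6 ran from 0.0586 to 0.161. Without WT replicate 3 there were 4, without Rbm44 and Rwdd3 (adjusted p = 0.118) and Mcub (0.0623). Without TET2cKO replicate 1 there were 3, without Rbm44 (0.0816), Glrp1 and Gm22121 (0.0842) and Mcoln3 (0.0975). Without TET2cKO replicate 2 there were 3, and of the 7, Gbp2b and Glrp1 passed, the others lying between 0.0849 and 0.283. Without TET2cKO replicate 3 there were 3, and of the 7, Gbp2b and Gm22121 passed, the others lying between 0.0778 and 0.258.

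Of the 7 genes, 4 lie on chromosome 3, where Tet2 also lies: Rwdd3 starts at 121155397, Mcub at 129914960, Gbp2b at 142594816 and Mcoln3 at 146093277. Glrp1 (start 88499871) and Rbm44 (start 91144973) lie on chromosome 1, and Gm22121 had no position in the gene table. Chromosome 3 holds 933 of the 19759 genes with a position (4.72%). Among the genes named without passing, Dclk2, on chromosome 3, differed by 0.97 ± 0.13 (SE, adjusted p = 0.0978). On chromosome 1, Acadl (start 66830839), which encodes a long-chain acyl-CoA dehydrogenase, differed by -0.80 ± 0.11 (adjusted p = 0.0978), Wdfy1 (start 79702262) by 1.05 ± 0.16 and Gpr55 (start 85933221) by -1.19 ± 0.18 (adjusted p = 0.158 for both). Ifna4, an interferon alpha gene on chromosome 4, differed by -1.40 ± 0.20 (adjusted p = 0.133). Nnt, the mitochondrial transhydrogenase, on chromosome 13, differed by 0.60 ± 0.10 (adjusted p = 0.202).

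**Figure D2:**
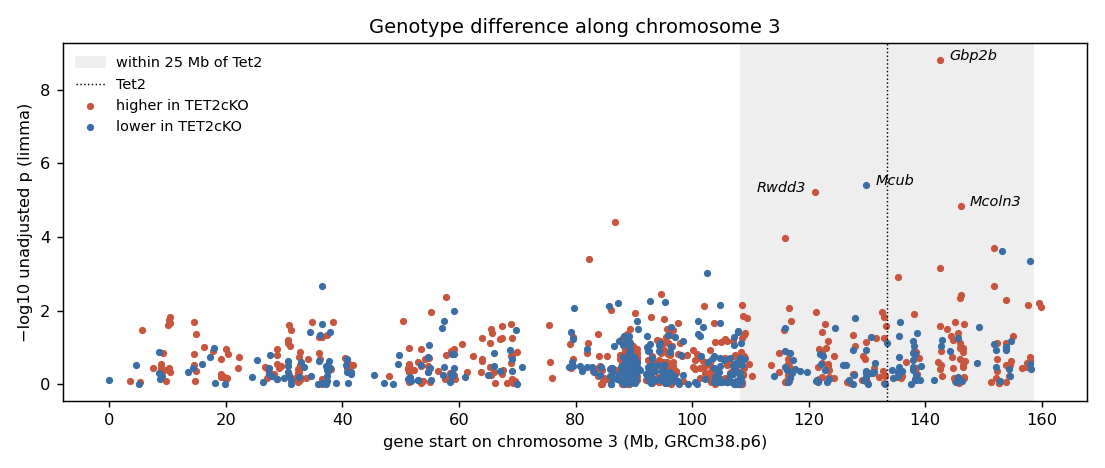
Each point is a tested gene, placed by its start on chromosome 3 in Mb (horizontal axis) and by -log10 of limma's unadjusted p (vertical axis), red where the value was higher in TET2cKO and blue where lower. Gbp2b, Mcub, Rwdd3 and Mcoln3 lie inside the grey band, which marks 25 Mb on either side of Tet2 (dotted line).

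Genes that mark effector and memory CD8+ T cells did not pass the test. The member with the smallest p was Gzmk in the list of effector molecules, at -0.52 ± 0.14 (SE, adjusted p = 0.533). In the list of the memory and naive program it was Klf2, at 0.39 ± 0.12 (adjusted p = 0.546). Gzmb, a granzyme, was at a log2 value of 13.4 in both genotypes, with a difference of 0.05 ± 0.09 (SE, adjusted p = 0.879). The cytokine genes Ifng and Tnf differed by -0.13 ± 0.11 and -0.08 ± 0.09. Prf1, which encodes perforin, differed by -0.43 ± 0.17 (adjusted p = 0.582), and Prdm1, a regulator of terminal effector differentiation, by -0.45 ± 0.13 (adjusted p = 0.542). Tbx21 differed by -0.09 ± 0.12, Klrg1 by -0.05 ± 0.12, Il2ra by -0.01 ± 0.09 and Pdcd1 by -0.13 ± 0.12. Among genes of naive and memory cells, Tcf7 differed by 0.22 ± 0.10 (adjusted p = 0.612), Eomes by 0.14 ± 0.10 and Il7r by -0.23 ± 0.14. Cd44, listed here among genes of activation and homing, differed by 0.24 ± 0.12. The homing receptor gene Ccr7 differed by 0.00 ± 0.11. The highest values of the 6 arrays lay between 13.84 and 13.89, so Gzmb, Ifng and Il2ra lie near the top of the scale, where differences may be compressed. Klrg1, at 5.29 in WT and 5.24 in TET2cKO, lies near the limit of the brightness filter, a log2 value of 4.673. Small differences at either end thus do not show that a gene was unchanged.

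Across the 32 lists, 584 of 662 genes were measured and 0 passed limma's adjusted p over all genes, while 55 had an unadjusted p under 0.05. Adjusted over the list alone, 4 memberships passed: Gbp3 and Ifi44 in the interferon list, Klrk1 in the list of innate-like receptors and Slc9b2 in the list of Tet2's neighbours. Gbp3 differed by 0.57 ± 0.11 (SE), Ifi44 by 1.05 ± 0.25, Klrk1, which encodes the receptor NKG2D, by -0.62 ± 0.11 and Slc9b2 by 0.56 ± 0.12. Gbp3, Ifi44 and Slc9b2 lie on chromosome 3.

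With camera's preset correlation, 6 of 28 lists passed, 4 higher and 2 lower in TET2cKO. Mitotic (G2/M) genes were higher in 29 of 31 members, with a median log2 difference of 0.11 (adjusted p = 0.00372, and adjusted p = 0.721 with an estimated correlation). Examples are Tpx2 at 0.24 ± 0.09 (SE) and Bub1 at 0.24 ± 0.09, both of which act at the spindle. Cholesterol synthesis genes were higher in 17 of 21 members, with a median of 0.12 (adjusted p = 0.00967, and adjusted p = 0.721 with an estimated correlation), among them Sc5d at 0.35 ± 0.13 and Cyp51 at 0.25 ± 0.10. DNA replication (S phase) genes were higher in 29 of 32 members, with a median of 0.10 (adjusted p = 0.0143, and adjusted p = 0.749 with an estimated correlation). Oxidative phosphorylation genes were higher in 28 of 34 members, with a median of 0.08 (adjusted p = 0.0143, and adjusted p = 0.749 with an estimated correlation). These 4 lists kept their direction under both other scalings, but after quantile normalization none passed, with adjusted p from 0.127 to 0.245, and the 8 lists then called were all lower. WT replicate 1 had the lowest list mean of the 6 arrays for cholesterol synthesis (10.35), S phase (10.40) and oxidative phosphorylation (10.03). Without it 2 lists passed, 1 of them among the 6, and the adjusted p was 0.0742 for cholesterol synthesis, 0.182 for S phase and 0.404 for oxidative phosphorylation. It was 0.0804 for S phase without TET2cKO replicate 3 and 0.086 for oxidative phosphorylation without TET2cKO replicate 2, and with a 50th percentile filter 0.0558 and 0.0531. Over all refits with the preset correlation it ran from 0.000244 to 0.127 for G2/M, 0.00196 to 0.139 for cholesterol synthesis, 0.002 to 0.223 for S phase and 0.002 to 0.404 for oxidative phosphorylation.

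Interferon-response genes were lower in 27 of 34 members, with a median log2 difference of -0.21 (adjusted p = 0.00372, and adjusted p = 0.749 with an estimated correlation). Irf7, a transcription factor of that response, differed by -0.34 ± 0.15 (SE) and Ifi27l2a by -0.26 ± 0.09, while Gbp3 and Ifi44 went the other way. The mean of the list was 8.92 ± 0.21 (SD, n = 3) in TET2cKO and 9.05 ± 0.28 in WT, with an exact permutation p of 0.5. Its camera adjusted p was 0.0742 without WT replicate 1, 0.357 without WT replicate 3, 0.111 without TET2cKO replicate 1 and 0.19 with array weights, over a range of 6.23e-11 to 0.357 in all refits. Targets of IL-2 and STAT5 were lower in 17 of 24 members, with a median of -0.03 (adjusted p = 0.0384, and adjusted p = 0.721 with an estimated correlation). Tnfrsf4, which encodes the costimulatory receptor OX40, differed by -0.53 ± 0.15 and Il10 by -0.34 ± 0.09. That call was lost without WT replicate 1 (adjusted p = 0.226), WT replicate 2 (0.119), TET2cKO replicate 1 (0.0685) or TET2cKO replicate 3 (0.167), with median centring (0.0635), with no filter on dim probe sets (0.0857) and with array weights (0.17), over a range of 0.00206 to 0.226.

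**Figure D3:**
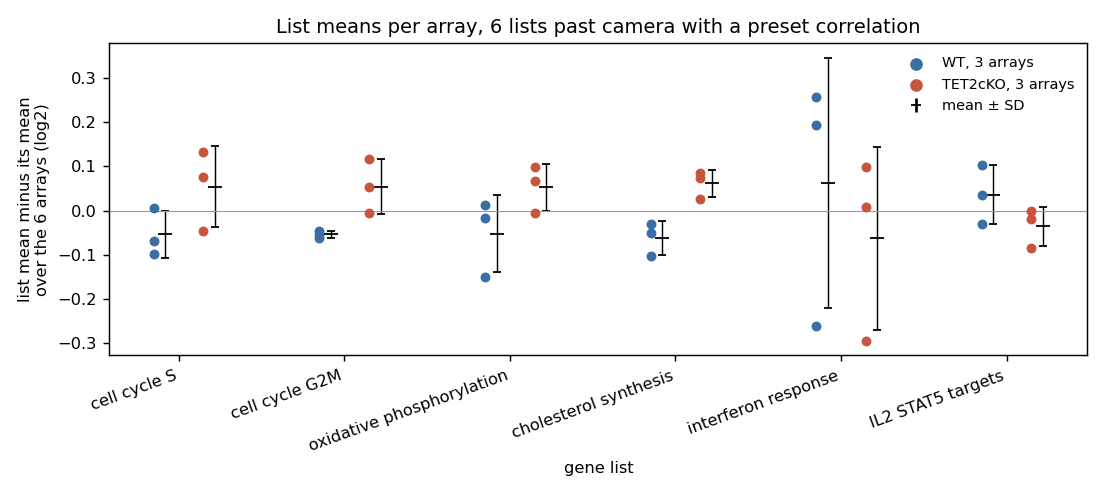
Mean of each of the 6 lists in each array, as the difference from its mean over the 6 arrays on the log2 scale (vertical axis), for the lists named on the horizontal axis, with WT in blue, TET2cKO in red and black bars for mean ± SD (n = 3). The interferon list spans 0.52 among WT arrays and 0.395 among TET2cKO arrays; the 4 higher lists no longer passed after quantile normalization.

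The other 22 lists did not pass camera with the preset correlation. Camera's adjusted p was 0.343 for effector molecules, 0.141 for the memory and naive program, 0.111 for effector regulators, 0.155 for inhibitory receptors and 0.539 for the DNA methylation machinery. It was 0.938 for glycolysis, 0.0662 for the ATF4 amino acid response, 0.155 for the unfolded protein response, 0.145 for genes induced by the T cell receptor and 0.732 for helper-lineage genes. It was 0.539 for homing receptors, 0.754 for apoptosis, 0.283 for innate-like receptors, 0.938 for ribosomal proteins, 0.965 for heat shock genes and 0.442 for the neighbours of Tet2. Camera compares a list with the other genes, and the median log2 difference over all genes tested was 0.0254. Its direction can thus be lower for a list whose own median is positive. That was so for helper-lineage, ribosomal, heat shock and B cell genes, whose medians were 0.01, 0.02, 0.02 and 0.06. The mean of the B cell genes, -0.02, had the sign of the test. Fry, testing for a shift in 1 direction, called 0 of 28 lists, with a smallest adjusted p of 0.268. Camera with an estimated correlation called 0, with a smallest of 0.721. At an unadjusted p under 0.05 they gave 2 and 0 lists, and camera with the preset correlation 9.

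Of the T cell identity genes, Cd8a was at a log2 value of 12.60 in TET2cKO and 12.66 in WT. Cd6 differed by -0.28 ± 0.10 (SE), Cd2 by -0.22 ± 0.10 and Cd5 by -0.23 ± 0.11, with adjusted p from 0.563 to 0.613. The list had 7 members higher and 13 lower, with a median difference of -0.02 (camera adjusted p = 0.145). Markers of other cell types were compared between the genotypes only, since the brightness of different probe sets does not rank the levels of their genes. The median log2 difference was 0.06 for B cell markers (adjusted p = 0.59), -0.04 for myeloid markers (0.27), 0.05 for markers of dendritic cells and MHC class II (0.965), 0.04 for erythroid markers (0.653) and 0.09 for CD4+ T cell markers (0.539). Ighm, an immunoglobulin heavy chain gene, was at 11.45 in TET2cKO and 11.53 in WT, and Cd4 at 5.44 and 5.26. Of the MHC class II genes, H2-Aa differed by 0.53 ± 0.18 (SE) and H2-Eb1 by 0.30 ± 0.10 (adjusted p = 0.563 for both). Neither overlapped between the genotypes, as was so for 13.8% of all genes tested. The WT mean of H2-Aa, 4.77, lies near the limit of the brightness filter, 4.673, so the size of its difference is uncertain. H2-Ab1 was at 10.88 in TET2cKO and 10.85 in WT. Markers of gamma-delta T cells (3 measured, median log2 difference 0.02) and of NK cells (4 measured, 0.21) were too few for a list test. The 4 measured Y-linked genes had a median difference of 0.10, and Xist, which lay under the brightness filter, was at 4.33 in TET2cKO and 4.37 in WT.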

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

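The refit without genes within 25 Mb of Tet2 and the test over all probe sets were chosen after seeing the data. The count of 7 genes was 6 to 10 with the workbook's values, median centring, no filter on dim probe sets, the mean of probe sets, an adjusted p of 0.10 and trend with robust eBayes. It was 4 after quantile normalization, 4 with a 50th percentile filter (which removed Rbm44, Glrp1 and Gm22121, while the other 4 passed), 15 with array weights, 3 without genes within 25 Mb of Tet2 (4 of the 7 removed by construction) and 1 over all probe sets. At an unadjusted p under 0.05 with a 1.5-fold change there were 110 genes, and 2983 had groups without overlap. Leaving out 1 array gave 1 to 9 genes. The values showed no pairing by replicate number: deviations of same-numbered arrays correlated at -0.103, -0.059 and -0.056, and 0 of 6 arrays correlated best with their own number. The labels do not say what the numbers mark, and with 3 arrays per genotype a weak pairing could be missed. A replicate block gave 1 gene and left 6 lists. Apart from the genes removed by construction, the cause of these moves was not tested.

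The Tet2 difference ran from -0.39 to -0.12 over the arrays left out, and never passed. The count of 6 lists was 10 with a 50th percentile filter, 10 with trend and robust eBayes, 0 with an estimated correlation and 0 with fry, and 2 to 7 when 1 array was left out. Quantile normalization gave 8 lists, all lower, of which 2 were among the 6. Over the named genes, 2138 values kept their side of the threshold, 30 lost the call, 11 gained it and 32 uncalled values changed sign. Most of the values kept belong to genes not called in the main test, which had no call to lose. Of 15 refits that held each called gene, Gbp2b passed in 15, Glrp1 in 11 and Rwdd3 in 10. Mcub passed in 9, Rbm44 in 8 and Mcoln3 in 7. Over single lists, 375 values kept their side, 22 lost the call, 22 gained it and 25 uncalled ones changed sign. The 22 losses all fell among the 6 lists called in the main test. No called value changed sign. Genes near the 25th percentile of brightness may have little signal over background, which was not measured here, so small differences there may be missed.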

Other observations

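The count over other splits of the samples was planned; the other tests in this part, and the genes first named here, were chosen after the results were seen. Of 237 tested genes within 25 Mb of Tet2, 17 had an unadjusted p under 0.01 (7.17%), against 321 of 19522 elsewhere (1.64%). Of the 17, 14 were higher in TET2cKO and 3 lower. Ifi44l, next to Ifi44, with a WT mean of 3.77 under the limit of the brightness filter, differed by 1.84 ± 0.30 (SE, limma adjusted p = 0.23), and Slc9b2 by 0.56 ± 0.12 (adjusted p = 0.423). Mcoln2, beside Mcoln3, differed by 0.34 ± 0.09 (adjusted p = 0.528). St6galnac3 differed by -0.63 ± 0.11 and Cth, which encodes an enzyme of cysteine synthesis, by -0.60 ± 0.11 (adjusted p = 0.238 and 0.328). Wls, just beyond that window, had log2 values of 9.72 and 9.87 in TET2cKO replicates 1 and 3 but 7.49 in replicate 2, against 7.07 to 7.37 in WT (adjusted p = 0.542). On chromosome 1, the bin from 60 to 80 Mb, which holds Acadl and Wdfy1, had 8 genes with an unadjusted p under 0.01 where 2.33 were expected, and a share of 0.906 of circular shifts gave a higher excess in some bin. Among the 4672 probe sets with no symbol or several, limma called 0 and 390 had an unadjusted p under 0.05.

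The real split of the 6 arrays gave 7 genes past the threshold and the highest of the other splits gave 0, so 1 of 10 splits reached that number. With 10 splits the share cannot fall under 0.05. At an unadjusted p under 0.05 the real split gave 1793 genes, while setting WT replicate 1 with TET2cKO replicates 2 and 3 against the rest gave 1987, so counts at that threshold do not single out the genotype.

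The changed genes gathered on chromosome 3 around Tet2. An odds ratio of 3.56 argues against an effect of TET2 loss spread evenly over the genome as the only source of this gathering. That ratio is for p under 0.01 within 25 Mb of Tet2 with the called genes left out (circular-shift permutation p = 0.00643). With those genes, which prompted the test, it was 4.62. The genes left in still include Gbp3 and Mcoln2, beside the called Gbp2b and Mcoln3, so the test is not free of what prompted it. Whether TET2 loss also changed genes elsewhere is not answered by it. A probe mismatch carried by TET2cKO, which lowers signal, is argued against by the 14 genes that were higher. For the 3 lower genes a mismatch cannot be told apart from lower expression. A candidate explanation, as a hypothesis, is a segment from another strain that stayed linked to the floxed allele, which predicts the same odds ratio above 1, and Gbp2b is known to be poorly induced in C57BL/6 mice. Local effects of the altered Tet2 locus on its neighbours predict it too. The list of Tet2's neighbours did not pass camera (adjusted p = 0.442), with 12 members higher and 8 lower. Camera looks for a shift in 1 direction and can miss changes in both. Fry's test for changes in both directions gave that list an unadjusted p of 0.00381, and 0.107 after adjustment over the lists. It did not pass, and it cannot tell local effects from a linked segment, so local effects stay open. For linked segments on other chromosomes the evidence was undecided. The highest count in a 20 Mb bin, 8, was reached in a share of 0.9997 of circular shifts. That count favours gene-dense bins, and the fixed edges of the bins part the named genes of chromosome 1. The highest excess over the number of genes expected in a bin was reached in a share of 0.0795. It lay on chromosome 4 from 80 to 100 Mb, with 8 genes, Ifna4 among them, where 1.345 were expected.

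The 4 lists that were higher in TET2cKO hold bright genes, and the median log2 difference was 0.063 in the brightest 25% of all genes against -0.038 in the dimmest 25%. For oxidative phosphorylation and S phase the median lay at the 89.0th and 97.47th percentile of 10000 random lists matched on brightness, the latter just inside the central 95% of them, which is consistent with a difference between arrays that depends on intensity. For G2/M (99.28th) and cholesterol synthesis (99.03rd) the medians lay above that range. Lists that camera did not call also lay outside it, such as innate-like receptors (99.94th), T cell identity (0.22nd) and the unfolded protein response (0.02nd). Lying outside the range is thus not particular to the called lists. Quantile normalization ended the G2/M and cholesterol synthesis calls (camera adjusted p = 0.127 and 0.139). Their medians shrank from 0.106 to 0.039 (SD over members, which are not replicates, 0.078 and 0.075) and from 0.117 to 0.062 (SD 0.115 and 0.111). After that scaling the G2/M list mean differed by 0.052, with an SD over arrays of 0.01 in WT and 0.022 in TET2cKO. For cholesterol synthesis the difference was 0.069, with SDs of 0.053 and 0.027. Before it, the arrays of the genotypes did not overlap in these 2 lists (exact permutation p = 0.1, the smallest possible). That p was 0.2 for S phase and oxidative phosphorylation. Part of each difference thus went with the scaling and part stayed, with 23 of 31 and 14 of 21 members still higher, so intensity and genotype cannot be told apart there. The matched lists take genes as independent, while the smallest camera adjusted p of the 4 was 0.721 with an estimated correlation. That correlation was 0.253 for G2/M, 0.342 for S phase and 0.376 for oxidative phosphorylation. It was 0.0589 for cholesterol synthesis, with an unadjusted camera p of 0.0715. Members that vary together between arrays may thus also account for the calls, least clearly for cholesterol synthesis. An effect of genotype stays open.

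The interferon-response list was lower in TET2cKO by a mean of -0.126, less than its range of 0.52 within WT and 0.395 within TET2cKO, which is consistent with variation between arrays that does not follow genotype. The lowest WT array minus the highest TET2cKO array was -0.361, so the genotypes overlapped. That overlap does not exclude a lower interferon response without TET2, which 3 arrays per genotype with this spread cannot show or rule out.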
